A study of Sus scrofa with 37 samples.

How the data were processed

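Gene expression in the pancreas and in cultured islets of pigs had been measured by RNA sequencing, and the deposited values are whole-number read counts per Ensembl pig gene, 1 column per library, in a table for each tissue. The submitters' processing notes name FastQC, HISAT2 2.0.2, Subread and edgeR and the genome build susScr3, with no role or order. The counting options, the strand setting and the annotation release are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies are uncertain. The counts were used as deposited, with no rounding or scaling. The tables hold 25880 gene identifiers, of which 14857 were matched to a symbol through a table of Ensembl identifiers. A RefSeq gene table of assembly Sscrofa11.1 served only to see which genes adjoin, because the submitters name another build, and no coordinates are given. Which build the counts were made on was not checked.

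Samples were grouped by the tissue in the title and the density label, both per the labels. Columns were matched to samples by animal code and tissue, which gave 35 columns for 37 samples. There was 1 column that matched no sample, and it was not used. The islet library of animal 12AS51, whose density label reads N/A, entered only the comparison of tissues. The titles of 2 islet samples (animals 11KS28 and 12AS51) say islets while their source name says pancreas, and the title was followed. Replicate numbers follow the listed order, and the animal code is what pairs libraries across tissues. The pairing was checked from expression. The correlation of expression deviations between the tissues of an animal was highest for the same animal in 0 of 16 animals (permutation p = 1, 100000 permutations) and in 2 of 16 with the 500 most variable genes (permutation p = 0.26). The presence of counts of the Y-linked genes KDM5D and EIF1AY (at least 3 together) matched in 15 of 16 animals. In the pancreas of 12FS135, 1 count was seen where 22.8 were expected from other animals (one-sided Poisson p = 3.01e-09). After scaling by the acinar share 1.69 were expected (one-sided Poisson p = 0.498). These genes need not follow the acinar share, so whether this library belongs to its animal stays open. The 6 pancreas libraries with an animal code that begins with 14 matched by the absence of such counts. Their totals were low too. With about 22.8 counts expected, absence would be informative, but with about 1.69 it could occur in an animal that has these genes. Many animals share the presence or the absence, so a match does not show which animal a library came from. The labels say that libraries with a shared code come from the same animal, and the animal was therefore used as a block in alternative fits. No 2 libraries of a group were identical among 128 pairs, and the lowest chi-square per degree of freedom between them was 3.22, so all were kept as separate replicates.

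The depth was 265000 to 6702589 gene counts per library, and the floor was set at 3 counts. Shares of single libraries carry 95% Wilson intervals. Counts scaled to a library total of 1000000 (CPM) printed as means ± SD use the library total. Means and fold changes of genes can therefore differ in size and sign, because the tests use scaled library sizes.

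Genes were tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM scaling and the robust quasi-likelihood test, two-sided, at a Benjamini-Hochberg adjusted p of 0.05. The comparisons were High against Low within pancreas, High against Low within islets, islets against pancreas, and the difference between the density differences of the tissues. A set of 27 gene lists with 472 entries was fixed beforehand. They cover pan-endocrine, beta cell, alpha cell, delta and PP cell, acinar, ductal, fibroblast and stellate, endothelial, myeloid, lymphocyte, Schwann and neural, adipocyte and erythroid genes, islet transcription factors, glucose sensing and exocytosis, proliferation, immediate early genes, heat shock, unfolded protein response, oxidative phosphorylation, glycolysis and hypoxia, ribosomal proteins, cholesterol synthesis, interferon response, inflammation, antigen presentation and insulin-like growth factor signalling. Some genes stand in more than 1 list, such as NKX6-1 among beta cell genes and islet transcription factors. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Fry tests whether a list moves, on balance, in a given direction, and does not compare it with other genes. List levels per library were means of log2(CPM + 1). Endocrine and acinar shares were sums over 53 and 17 genes. Both were compared between density groups with an exact two-sided permutation test over 24310 splits (scipy 1.17.1).

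Genes named in the text follow a rule fixed with the design. It takes, among genes that pass with a symbol and a mean of at least 1 CPM in the higher group, the 10 largest changes in each direction, or the 5 smallest p-values where fewer than 5 genes pass, up to 4 members with the smallest p of each list described, the 4 hormone genes INS, GCG, SST and PPY, the 5 most abundant genes of each tissue, of which those with a symbol or shared by both tissues are described, and the 5 smallest p-values of the difference between tissues. The results of some genes that this rule takes are not reported here. The genes KDM5D, EIF1AY, CEL, ALB, FGB, APOB, TP53I11, DNAJB1 and FOSB and the olfactory receptor genes were chosen after their values were seen. The groups, the lists, the tests and most alternatives were chosen before the data were examined.

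Alternatives included relative log expression and upper-quartile scaling, no low-count filter and a filter of 1 CPM, DESeq2 1.42.0 and limma-voom, leaving out each library in turn, covariates for the leading digits of the animal code, the number in the title in blocks of 10 (1 to 10, 11 to 20, 21 to 30 and 31 to 40), the acinar and the pan-endocrine level, the density label of the animal's other tissue, only animals with the same label in both tissues, and the animal as a block. Chosen after the data were seen were fits with only libraries above 1000000 counts, counts thinned to 265000 per library, the log2 total or the presence of KDM5D and EIF1AY as a covariate, genes above 5% of a library left out, shallow or atypical libraries left out, TMM-scaled list levels, and shares with each library left out. For each comparison 100 splits of the same libraries, the real one included, were counted for results as large.

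The gene tests were tested on simulated data with 200 changed genes and the library sizes of the real groups. In the pancreas comparison (10388 genes) 21% of genes changed by a log2 of 1 and 75% of those changed by 2 were called, with 6 false calls. In the islet comparison (11953 genes) the shares were 78% and 97% with 10 false calls, and in the tissue comparison (12237 genes) 75% and 94% with 5. The direction was right in 100% of the calls. Figures were drawn with matplotlib 3.10.9.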

Results

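To characterise how gene expression varies with islet density, RNA had been sequenced from the pancreas and from isolated islets of pigs. Islets are the clusters of hormone-secreting endocrine cells that lie within the exocrine pancreas, where acinar cells make digestive enzymes and duct cells carry them away. Per the labels, a pancreas sample was a 50 mg piece of the duodenal lobe taken when the organ was retrieved, and an islet sample was purified from the organ and kept in floating culture for 7 days. Each sample has a density label of High or Low, and the titles carry a code for the animal. Of 37 samples, 35 had a column of counts. They were 8 High and 9 Low pancreas libraries, 8 High and 9 Low islet libraries, and the islets of animal 12AS51, which have no density label. Both tissues were counted in 16 animals. The islet samples of animals 15LS27 and 15LS30 were not analysed here. The labels do not say how density was measured.

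The islet libraries held 3237653 to 6702589 gene counts, and the High pancreas libraries held 1855075 to 3922006. The Low pancreas libraries were uneven. Low replicates 2 and 9 (animals 12FS161 and 15LS30) held 2234639 and 1884982, and the other 7 held 265000 to 536014. These 7 are called the shallow libraries from here on, and they include all 6 animals of both tissues whose code begins with 14, every one of which was labelled Low. A level of 3 counts, taken as the floor, was worth 5.60 to 11.3 CPM (counts scaled to a library total of 1000000) in the shallow libraries and 0.448 to 1.62 CPM in the others. The 10 most abundant genes held a median of 61.9% of counts in the shallow libraries and 41.0% in the other 10 pancreas libraries. In the islets they held 21.8% to 52.3% of counts in the 17 libraries with a density label. Floors and intervals cover counting error only.

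**Figure D1:**
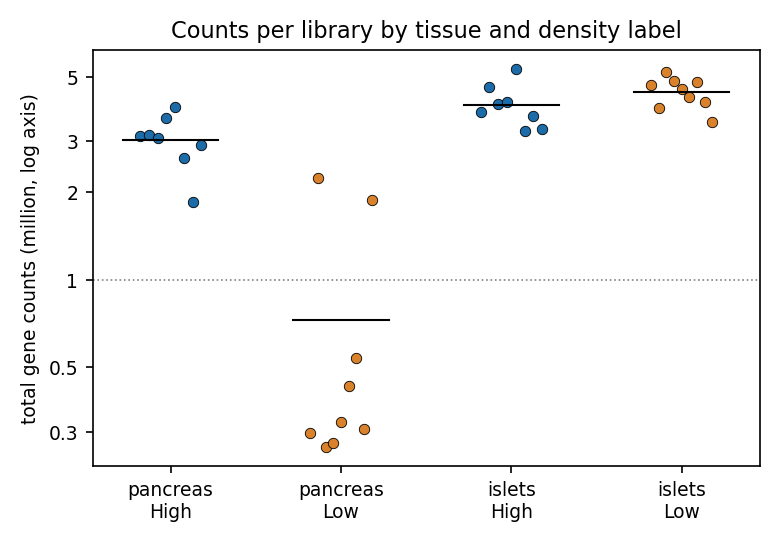
Total gene counts of each library on a log axis, by tissue and density label; points are libraries, horizontal bars are group means and the dotted line marks 1000000 counts. Of the 9 Low pancreas libraries, 7 lie between 265000 and 536014, below every other library.

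To examine what distinguished the purified islets from the organ, the 18 islet libraries were compared with the 17 pancreas libraries. Hormones and the proteins that store and process them were higher in islets, and digestive enzymes were higher in pancreas. INS (ENSSSCG00000033740), which encodes insulin, averaged 36834 ± 14309 CPM (SD, n = 18) in islets and 874 ± 1838 CPM (SD, n = 17) in pancreas, a log2 fold change of 5.08 (SE 0.52). GCG (ENSSSCG00000015895), the glucagon gene, rose by 4.75 (SE 0.49), SST (ENSSSCG00000033815), somatostatin, by 4.55 (SE 0.36), and PPY (ENSSSCG00000017368), pancreatic polypeptide, by 2.96 (SE 0.48). The neuropeptide gene GAL (ENSSSCG00000012883) rose most, by 6.11 (SE 0.72). The granule proteins CHGB (5.79, SE 0.48) and CHGA (5.30, SE 0.48) followed, then VGF (5.23, SE 0.52), RAB39A (5.21, SE 0.40), SCG3 (5.10, SE 0.48), SCG5 (5.08, SE 0.40), the prohormone convertase PCSK2 (5.08, SE 0.44) and TTR, transthyretin (4.96, SE 0.41). For these genes the highest adjusted p was 1.01e-06, for PPY (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, as for each adjusted p of a gene).

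The largest falls were in products of acinar cells. CPB1 (ENSSSCG00000011694), a carboxypeptidase, averaged 4.25 ± 7.70 CPM (SD, n = 18) in islets and 16468 ± 14298 CPM (SD, n = 17) in pancreas, a log2 fold change of −12.41 (SE 0.87). PNLIP, pancreatic lipase, changed by −12.40 (SE 0.86), the elastase CELA2A by −12.33 (SE 0.81), the lipase-related PNLIPRP1 by −12.08 (SE 0.95) and the phospholipase PLA2G1B by −12.06 (SE 0.90). SYCN, a zymogen granule protein, changed by −11.94 (SE 0.69), PDIA2, a pancreatic disulfide isomerase, by −11.92 (SE 0.50), the trypsinogen PRSS2 by −11.91 (SE 0.90), GALNT6 by −11.66 (SE 0.66) and the colipase CLPS by −11.59 (SE 0.72). The highest adjusted p among these 10 was 2.71e-14. The values of trypsin and elastase genes are uncertain where near-identical copies share reads. GALNT6 adjoins the elastase gene CELA1 in the RefSeq annotation of Sscrofa11.1, and CELA1 matched no identifier, so counts of GALNT6 can hold reads of its neighbour. The most abundant genes of both tissues included a pair of identifiers without a symbol. ENSSSCG00000018061 averaged 134554 ± 84789 CPM (SD, n = 18) in islets and 82500 ± 33322 CPM (SD, n = 17) in pancreas (log2 fold change 1.47, SE 0.60, adjusted p = 0.0303). ENSSSCG00000018063 averaged 94702 ± 56933 and 103495 ± 63349 CPM and did not pass (0.62, SE 0.60, adjusted p = 0.377). Both estimates turned to −0.14 (adjusted p = 0.743) and −1.03 without the 2 islet libraries whose source name reads Pancreas, the latter passing as lower in islets (adjusted p = 0.0175), as it did with DESeq2 (−0.97, adjusted p = 0.000695), and with the animal as a block the former was −0.055 (adjusted p = 0.924). The mitochondrial gene COX1 rose by 1.37 (SE 0.42, adjusted p = 0.0042), by 0.61 with the animal as a block (adjusted p = 0.0832) and by 0.56 without the 2 libraries (adjusted p = 0.0699).

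In all, 7726 of 12339 tested genes passed an adjusted p of 0.05, 3834 higher and 3892 lower in islets, and 2881 passed a test for a change of more than 2-fold (edgeR glmTreat). With upper-quartile scaling the median log2 fold change of all genes moved from −0.01 to −0.14. Of the gene lists fixed beforehand, 11 passed camera with its preset correlation of 0.01. With an estimated correlation 3 did, and 5 did when the animal was also fitted as a block. All 21 tested pan-endocrine genes rose, PAX6, an islet transcription factor, among them by 4.05 (SE 0.27). The list passed with adjusted p = 1.34e-16, and adjusted p = 0.016 with an estimated correlation. Of 11 beta cell genes 9 rose and 1 fell (2.16e-05, and adjusted p = 0.016 with an estimated correlation). They included the zinc transporter SLC30A8 (3.94, SE 0.27), the sulfonylurea receptor ABCC8 (3.92, SE 0.27) and NKX6-1 (3.60, SE 0.30). All 15 acinar genes fell, with a median of −10.54 (9.79e-21, and adjusted p = 0.0293 with an estimated correlation). RBPJL, an acinar transcription factor, changed by −10.54 (SE 0.43).

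The other 8 lists that passed with the preset correlation did not pass with an estimated one when no block was fitted, and all 8 passed fry. Of 10 alpha cell genes 7 rose and 1 fell (adjusted p = 0.0157, and adjusted p = 0.129 with an estimated correlation). The amino acid transporter SLC7A2 rose by 2.91 (SE 0.23). Of 16 islet transcription factors 12 rose and 2 fell (0.00152, and adjusted p = 0.06 with an estimated correlation). GATA4 was one that fell (−4.10, SE 0.30). With the animal as a block and an estimated correlation these 2 lists passed, both at adjusted p = 0.035. In the list of glucose sensing and exocytosis genes 13 of 16 rose and 1 fell (8.12e-07, and adjusted p = 0.06 with an estimated correlation), among them the calcium channel gene CACNA1D (2.82, SE 0.18). In the unfolded protein response list 9 of 19 rose and 4 fell (0.0289, and adjusted p = 0.624 with an estimated correlation). The chaperone HSPA5 rose by 2.13 (SE 0.33) and MANF by 1.84 (SE 0.16), and CRELD2 changed by −2.44 (SE 0.20). Duct genes were lower, 9 of 15 with 3 higher (0.00397, and adjusted p = 0.29 with an estimated correlation). SLC4A4, a bicarbonate transporter, changed by −6.64 (SE 0.43), TFF2 by −10.18 (SE 0.69) and SOX9 by −3.75 (SE 0.29). TFF2 lay near the acinar median of −10.54, so its fall need not come from duct cells. Of 12 endothelial genes 9 fell and none rose (0.0151, and adjusted p = 0.296 with an estimated correlation), with the angiopoietin receptor TEK at −4.82 (SE 0.28). Of 9 myeloid genes 5 fell and none rose (0.00384, and adjusted p = 0.165 with an estimated correlation), with the macrophage receptor CD163 at −5.92 (SE 0.37) and PTPRC at −2.42 (SE 0.25). Of 8 antigen presentation genes 7 fell and 1, TAPBP, rose (0.0127, and adjusted p = 0.06 with an estimated correlation). NLRC5 changed by −3.29 (SE 0.26), CD74 by −3.30 (SE 0.27) and TAPBP by 1.25 (SE 0.13).

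The remaining lists did not pass camera. Of 15 fibroblast and stellate genes 8 rose and 6 fell (adjusted p = 0.813), PDGFRA changing by −3.82 (SE 0.26) and SPARC by 1.93 (SE 0.24). Their median was 0.62, their mean −0.39 and the test pointed down. Of 12 immediate early genes 4 rose and 2 fell (0.813), with MYC at −4.91 (SE 0.28) and FOS at 2.79 (SE 0.48). Their median was 0.33 and the test pointed down. The other counts of genes higher and lower were 9 and 5 of 16 for cholesterol synthesis (0.253), 6 and 4 of 13 for insulin-like growth factor signalling (0.813, IGF1 at −6.49, SE 0.37), 7 and 1 of 11 for heat shock (0.0604) and 8 and 2 of 20 for oxidative phosphorylation (0.133). They were 6 and 4 of 16 for glycolysis and hypoxia (0.415), 1 and 4 of 23 for ribosomal proteins (0.623), 1 and 8 of 12 for the interferon response (0.129), 2 and 1 of 5 for Schwann and neural genes (0.813) and 1 and 1 of 7 for proliferation (0.813). The insulin-like growth factor list had a median of 0.62 and a mean of −0.35 with the test down. The ribosomal list had a median of −0.08 with the test up, and the proliferation list a median of −0.05 and a mean of 0.02 with the test down. Lists with fewer than 5 tested genes were not tested as lists. They had 3 higher and 1 lower of 4 for delta and PP cells, 0 and 2 of 4 for inflammation, 0 and 1 of 2 for adipocytes and 0 and 1 of 1 for lymphocytes, and no erythroid gene was tested. Adjusted over the list alone, the counts differed for endothelial genes (10 lower), myeloid genes (6 lower) and insulin-like growth factor genes (7 higher and 5 lower).

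To find genes that differed with the density label in the organ, the 8 High pancreas libraries were compared with the 9 Low ones. Acinar products were higher in High libraries. KLK1 (ENSSSCG00000024668), tissue kallikrein, averaged 1021 ± 409 CPM (SD, n = 8) in High and 120 ± 164 CPM (SD, n = 9) in Low, a log2 fold change of 3.25 (SE 0.53, adjusted p = 0.00011). CELA2A rose by 2.90 (SE 0.43), PRSS2 by 2.76 (SE 0.52), CPB1 and the carboxypeptidase CPA1 by 2.72 each (SE 0.49 and 0.46), PLA2G1B by 2.71 (SE 0.47), PNLIP and the ribonuclease RNASE1 by 2.67 each (SE 0.45 and 0.44), SERPINI2 by 2.64 (SE 0.47) and the ribosomal protein gene RPS12 by 2.61 (SE 0.51). The highest adjusted p among these 10 genes was 0.000528.

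The largest fall was that of SNORA66 (ENSSSCG00000018448), with a median of 289 counts per shallow library, and the next 9 were in genes with low counts. SNORA66, a small nucleolar RNA gene whose reads cannot be told from those of a host gene, averaged 18.7 ± 14.5 CPM (SD, n = 8) in High and 690 ± 386 CPM (SD, n = 9) in Low, a log2 fold change of −5.51 (SE 0.71, adjusted p = 2.92e-05). MYO7B changed by −5.22 (SE 0.77), SUSD4 by −5.18 (SE 0.66), the cell cycle factor E2F2 by −5.03 (SE 0.71), OTOG by −5.01 (SE 0.71), FAM135B by −4.92 (SE 0.68), the transporter SLC17A2 by −4.91 (SE 0.67), the receptor ADGRB2 and the macrophage receptor MARCO by −4.85 each (SE 0.67), and the erythrocyte anion exchanger SLC4A1 by −4.84 (SE 0.69). The highest adjusted p of these genes was 4.88e-05. Behind the 9 protein-coding ones stood median counts of 6 to 15 per shallow library.

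The hormone genes, which mark the islets within the organ, did not pass as higher in High. INS averaged 711 ± 509 CPM (SD, n = 8) in High and 1019 ± 2545 CPM (SD, n = 9) in Low (log2 fold change −0.09, SE 0.70, adjusted p = 0.93). Low replicate 9 (animal 15LS30) held 7803 CPM of INS, and the other Low libraries 67.5 to 297. Without that library INS rose in High by 1.86 (adjusted p = 0.000379). DESeq2 gave 1.77 (adjusted p = 1.69e-05) with its default settings, which can replace outlying counts in groups of this size. Whether the INS count of that library was replaced was not checked, so the DESeq2 value is not separate support. GCG changed by 0.49 (SE 0.64, adjusted p = 0.559), and by 1.97 without that library (adjusted p = 0.000461), and PPY by −0.17 (SE 0.72, adjusted p = 0.872). SST was lower in High (−0.94, SE 0.37, adjusted p = 0.0479), a call that held with upper-quartile scaling and limma-voom. It ended with relative log expression scaling (adjusted p = 0.054), no low-count filter (0.246), a filter of 1 CPM (0.166) and DESeq2 (0.111), with the leading digits of the animal code, the acinar level, the pan-endocrine level or the log2 total as a covariate (0.0612, 0.31, 0.105 and 0.189), and without genes above 5% of a library (0.0541). It also ended in animals with the same label in both tissues (0.164), with the label of the other tissue (0.59, adjusted p = 0.423), and on leaving out any 1 of High replicates 2, 3, 5, 6, 7 and 8 (−0.91 to −0.76, adjusted p = 0.0708 to 0.115) or Low replicates 8 (−0.99, adjusted p = 0.0516) and 9 (−0.55, adjusted p = 0.215).

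Across the organ 4283 of 10634 tested genes passed, 1998 higher and 2285 lower in High. With upper-quartile scaling 1467 were higher and 2772 lower, and the median log2 fold change of all genes moved from 0.07 to −0.11. Camera with the preset correlation passed 7 lists, and none passed with an estimated correlation. Of 16 acinar genes 15 were higher (adjusted p = 1.43e-08, and adjusted p = 0.377 with an estimated correlation). Of 23 ribosomal protein genes 22 were higher (4.00e-11, and adjusted p = 0.377 with an estimated correlation), RPSA by 2.26 (SE 0.35) and RPL10 by 2.10 (SE 0.34). Such genes have many processed copies in mammals, so their counts are uncertain. In the unfolded protein response list, whose members fold and clear secretory proteins, 15 of 19 rose and 1 fell (0.00023, and adjusted p = 0.523 with an estimated correlation). EDEM1 rose by 1.78 (SE 0.37) and PDIA4 by 1.68 (SE 0.35). Duct genes were higher in 9 of 15 cases and lower in 1 (0.0263, and adjusted p = 0.523 with an estimated correlation). The chloride channel CFTR rose by 1.40 (SE 0.30) and TFF2 by 2.41 (SE 0.39). TFF2 lay near the acinar median of 2.38, so its rise need not come from duct cells. Of 11 heat shock genes 5 rose (0.0237, and adjusted p = 0.591 with an estimated correlation), with HSPD1 at 1.46 (SE 0.31) and HSPA8 at 1.37 (SE 0.38). Of 18 oxidative phosphorylation genes 8 rose (0.0263, and adjusted p = 0.377 with an estimated correlation), with ATP5F1A at 1.71 (SE 0.36) and COX4I1 at 1.27 (SE 0.32). The glucose sensing and exocytosis list was lower, with 8 of 14 genes down and 1 up (0.00208, and adjusted p = 0.377 with an estimated correlation). SYT7, a calcium sensor of exocytosis, changed by −1.88 (SE 0.35).

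The other lists did not pass in the pancreas. The pan-endocrine list had 1 gene higher and 7 lower of 16 (adjusted p = 0.348), the beta cell list 1 and 3 of 9 (0.468) and the alpha cell list 0 and 1 of 6 (0.803). The myeloid list had 4 of 10 lower and none higher (0.064), with ITGAM at −2.69 (SE 0.47) and AIF1 at −2.75 (SE 0.63). Counts of higher and lower genes were 0 and 4 of 14 for fibroblasts (0.483), 4 and 1 of 11 for endothelium (0.803), 3 and 2 of 12 for islet transcription factors (0.803), 1 and 0 of 12 for immediate early genes (0.531), 2 and 3 of 14 for glycolysis and hypoxia (0.958) and 4 and 2 of 14 for cholesterol synthesis (0.562). They were 3 and 0 of 13 for the interferon response (0.803), 1 and 0 of 5 for inflammation (0.803), 1 and 2 of 7 for antigen presentation (0.531) and 3 and 3 of 10 for insulin-like growth factor signalling (0.803). The islet transcription factors had a median of −0.13 and a mean of −0.24 with the test up, and glycolysis a median of 0.05 and a mean of −0.24 with the test up. With fewer than 5 tested genes, delta and PP cells had 1 higher and 2 lower of 4, Schwann and neural genes 0 and 3 of 4 (GFAP at −4.13, SE 0.53, and NCAM1 at −2.06, SE 0.40), adipocytes 2 and 1 of 3 and proliferation 0 and 1 of 2 (MCM3 at −2.77, SE 0.48). Adjusted over the list alone, the counts differed for pan-endocrine genes (1 higher, 9 lower), alpha cell genes (0 lower), fibroblast genes (3 lower), heat shock genes (6 higher) and interferon genes (2 higher).

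Summed over the acinar list, 20.1% ± 2.77 (SD, n = 8) of counts in High and 3.66% ± 4.0 (SD, n = 9) in Low were acinar, an 8.21-fold difference of geometric means (exact two-sided permutation test, p = 0.000165, with 24310 splits). The High libraries ranged from 17.1% to 26% and the Low ones from 1.14% to 11.2%, so the ranges did not overlap. The endocrine share, over 53 genes, was 0.205% ± 0.0992 (SD, n = 8) in High and 0.286% ± 0.579 (SD, n = 9) in Low. On the log2 scale it was 0.59 higher in High (exact permutation p = 0.354), opposite in sign to the difference of means, and 1.07 higher without Low replicate 9 (exact permutation p = 0.0014). Mean log2 levels of the 27 lists per library were compared in the same way, and 14 passed after adjustment. Higher in High were ribosomal (2.57), acinar (2.48), unfolded protein response (1.59), oxidative phosphorylation (1.20), ductal (1.05) and heat shock genes (1.0). Lower were lymphocyte (−1.72), Schwann and neural (−1.65), proliferation (−1.58), erythroid (−1.09), exocytosis (−0.97), myeloid (−0.90), adipocyte (−0.71) and inflammation genes (−0.42). The highest exact permutation adjusted p of the 14 was 0.0194. With TMM-scaled levels, a choice made after the data were seen, endothelial (0.89), cholesterol synthesis (0.87), interferon (0.68), immediate early (0.62) and glycolysis genes (0.40) also passed as higher (highest exact permutation adjusted p = 0.0453). Inflammation genes then no longer passed (−0.15, exact permutation adjusted p = 0.144), and the other 13 lists did. No gene of the lymphocyte and erythroid lists had enough counts for the gene tests. The Low means of the lymphocyte, proliferation, inflammation and erythroid levels, 2.64, 2.56, 2.47 and 1.79 as log2(CPM + 1), lie under the level of 3 counts in a shallow library. Those of the Schwann and neural, myeloid and adipocyte levels, 3.31, 3.18 and 3.01, lie between the lowest and the highest such level among the shallow libraries. Olfactory receptor genes together held a median of 248 CPM in the shallow libraries and at most 92.7 CPM in the other pancreas libraries.

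**Figure D2:**
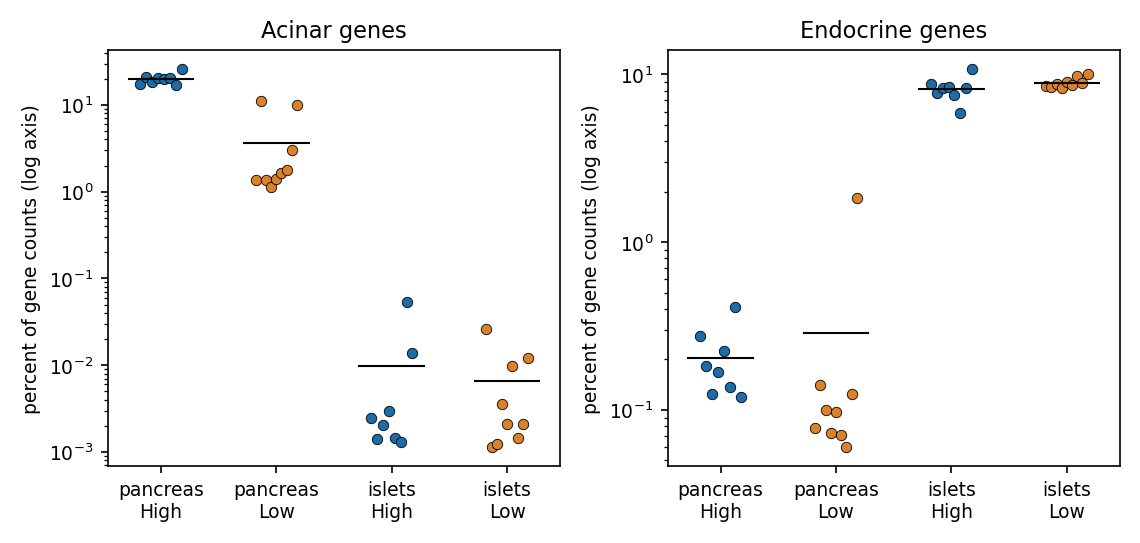
Percent of gene counts in acinar genes (left) and endocrine genes (right) per library on log axes, by tissue and density label; points are libraries and horizontal bars are group means. In pancreas the acinar share was 17.1% to 26% in High and 1.14% to 11.2% in Low; 1 Low pancreas library stands apart with 1.83% endocrine counts.

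With only the 10 libraries above 1000000 counts, 2 of them Low, no gene passed edgeR's test (1222 of 13217 at an unadjusted p under 0.05), the acinar share was 20.1% against 10.6% ± 0.761 (SD, n = 2), which gave the smallest exact permutation p that 45 splits allow, 0.0222, and no list level passed. Adjustment over 27 lists keeps that p above the threshold unless many lists reach it at once. The absence of a passing list level in these libraries therefore says little. Of the genes named above, these had smaller folds of the same sign there: KLK1 at 1.80 (SE 0.39), CELA2A at 1.78 (SE 0.49), CPA1 at 1.45 (SE 0.47), SLC17A2 at −3.48 (SE 1.02) and SNORA66 at −0.97 (SE 0.72). The call of SST ended with a larger fold (−1.72, SE 0.46, adjusted p = 0.33). In these libraries the endocrine share was lower in High (log2 difference −1.44, exact permutation p = 0.133), Low replicate 9 being 1 of the 2 Low libraries, and 8 lists passed camera with the preset correlation, the pan-endocrine list as lower (adjusted p = 2.91e-06). Of the lists tested both here and over all pancreas libraries, 19 kept their result, passing or not, 1 lost its call and 1 gained it. No High animal has a code that begins with 14, so with the leading digits of the code as a covariate the label is compared within the codes 12 and 15, which hold 3 Low pancreas libraries, and 368 genes passed, 34 higher and 334 lower. No gene passed with the acinar level as a covariate (615 at an unadjusted p under 0.05). The acinar share did not overlap between High and Low, so that covariate largely coincides with the label. That fit cannot show whether acinar content accounts for the calls.

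**Figure D3:**
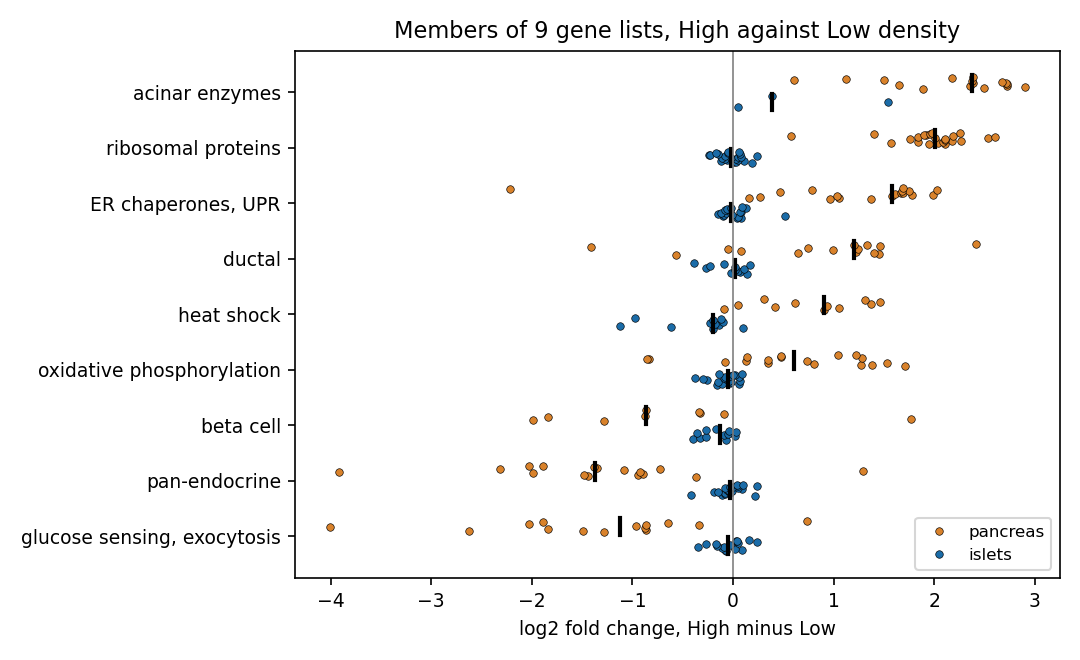
Log2 fold change, High minus Low, of each tested member of 9 gene lists in pancreas (orange) and islets (blue); points are genes and black bars are medians. In pancreas 15 of 16 acinar and 22 of 23 ribosomal protein genes passed as higher in High, and no islet gene passed.

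The same question was asked of the cultured islets by density label, with 8 High and 9 Low libraries. No gene passed edgeR's test among 12070, with 257 at an unadjusted p under 0.05, and none passed DESeq2 (297) or limma-voom (244). INS averaged 36941 ± 14008 CPM (SD, n = 8) in High and 40600 ± 9825 CPM (SD, n = 9) in Low (log2 fold change −0.05, SE 0.19). GCG differed by 0.13 (SE 0.34), SST by −0.46 (SE 0.43) and PPY by −1.11 (SE 0.48). The smallest p-values belonged to CNNM1 (−1.97, SE 0.51), the arginase gene ARG1 (−1.63, SE 0.42), NXN (−0.80, SE 0.22), the histone demethylase gene KDM6A (−0.52, SE 0.15) and the glutathione peroxidase gene GPX3 (−0.55, SE 0.16). All these genes had an adjusted p of 0.999. KDM6A differed by −0.10 (SE 0.16) once the presence of counts of KDM5D and EIF1AY, in 6 of 8 High and 1 of 9 Low libraries, was a covariate.

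Camera with the preset correlation passed 3 islet lists, all lower in High, none of which held with an estimated correlation, and fry passed none. Cholesterol synthesis genes had a median of −0.21 over 16 genes (adjusted p = 0.000425, and adjusted p = 0.43 with an estimated correlation), with MSMO1 at −0.49 (SE 0.19). Beta cell genes had a median of −0.13 over 12 genes (0.0375, and adjusted p = 0.43 with an estimated correlation), with G6PC2 at −0.27 (SE 0.15) and ENTPD3 at −0.40 (SE 0.29). Heat shock genes had a median of −0.20 over 11 genes (0.0381, and adjusted p = 0.857 with an estimated correlation), with DNAJA1 at −0.62 (SE 0.36) and HSPH1 at −0.97 (SE 0.63). The Low islets of 14HS26 and 14HS27 held 791 and 745 CPM of HSPH1, the other Low islets 74.9 to 153 CPM and the High islets 53.1 to 276 CPM. No member of any list passed, over all genes or adjusted over the list alone. Adjusted p-values of the other tested lists were 0.0584 for glycolysis and hypoxia, 0.0699 for oxidative phosphorylation, 0.075 for ribosomal proteins, 0.0791 for proliferation, 0.416 for endothelium, 0.496 for pan-endocrine, 0.498 for exocytosis, 0.543 for ductal genes and for islet transcription factors, 0.545 for antigen presentation and for insulin-like growth factor signalling and 0.584 for fibroblasts. They were 0.689 for myeloid, Schwann, immediate early and interferon genes, 0.735 for alpha cells and 0.962 for the unfolded protein response. Medians opposed the test in sign for ductal (0.02, with the test down), islet transcription factor (0.02, down), alpha cell (0.001, down) and Schwann genes (−0.06, up), and the means did so for alpha cell (0.05), endothelial (0.004) and unfolded protein response genes (0.01), all 3 with the test down. The acinar, delta and PP, lymphocyte, adipocyte and inflammation lists had fewer than 5 tested genes, with medians of 0.39, −0.40, 0.03, 0.44 and 0.09, and no erythroid gene was tested.

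The endocrine share of islet counts was 8.21% ± 1.36 (SD, n = 8) in High and 8.93% ± 0.594 (SD, n = 9) in Low, a log2 difference of −0.13 (exact two-sided permutation test, p = 0.144). Without High replicate 8 (animal 16CS60), which held 10.8%, it was −0.19 (exact permutation p = 0.0028). The acinar share was 0.00986% ± 0.0181 (SD, n = 8) against 0.00661% ± 0.00832 (SD, n = 9; exact permutation p = 0.994). No list level differed between the groups. The smallest exact permutation p was 0.0155, for cholesterol synthesis genes at −0.31, with adjusted p = 0.418.

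Whether the density difference was unlike in the 2 tissues was tested directly over the 34 libraries with a density label. LRP8 (ENSSSCG00000003848), a reelin receptor, had an islet difference that exceeded the pancreas difference by 4.75 (SE 0.51, adjusted p = 9.27e-08). The ephrin gene EFNB3 (3.51, SE 0.42), the vesicle adaptor AP3B2 (3.83, SE 0.48), the sodium-calcium exchanger SLC8A3 (3.65, SE 0.46) and PCDHAC2 (2.46, SE 0.32) followed. In pancreas EFNB3 changed by −3.89 (SE 0.49), AP3B2 by −4.21 (SE 0.55), SLC8A3 by −4.01 (SE 0.50) and PCDHAC2 by −2.66 (SE 0.34). In islets the same 4 genes differed by 0.07 (SE 0.12), 0.06 (SE 0.11), 0.07 (SE 0.16) and 0.15 (SE 0.11) and did not pass. Of 14337 genes 5718 passed, 3183 with the larger value in islets and 2535 in pancreas. With upper-quartile scaling 3995 and 1670 did, and the median of all genes moved from 0.003 to 0.26, and to 0.15 with relative log expression scaling. None of the hormone genes differed between tissues in this way, with PPY at −1.05 (SE 0.95), GCG at −0.50 (SE 0.84), SST at 0.27 (SE 0.59) and INS at −0.06 (SE 0.89). Among animals with the same label in both tissues, whose Low pancreas libraries are all shallow, the islet difference was the lower for GCG (−3.47, adjusted p = 6.54e-06) and INS (−2.31, adjusted p = 0.000484), and with the animal as a block also for SST (−1.29, adjusted p = 0.0108). With only libraries above 1000000 counts 61 genes passed.

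Both tissues of 16 animals carried a High or Low label, and the labels were the same in 11 and differed in 5. Animals 12FS135, 12FS161 and 15LS30 had Low pancreas and High islets, and 15LS26 and 16IS5 had High pancreas and Low islets. Using only animals with the same label in both tissues, 2828 of 4949 pancreas genes passed and INS was 1.38 higher in High (adjusted p = 0.00599). The 6 Low animals of this choice are those with the code 14, and both deeper Low pancreas libraries drop out, so density, depth and animal code coincide in it. With the label of the animal's other tissue, no pancreas gene passed edgeR's test (2311 at an unadjusted p under 0.05). No islet gene passed edgeR's test with either choice (586 and 1200 at an unadjusted p under 0.05).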

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

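The fits to thinned counts, with only libraries above 1000000 counts and with the presence of KDM5D and EIF1AY as a covariate were chosen only after the data were seen, and so was the reading of the thinned result as a share of the genes tested.

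In 14 of 144 groups of values, 1 library stood apart from its group by more than Dixon's critical value, where chance does so in about 5% of groups, here 7.2. In the Low pancreas library of animal 15LS30, endocrine genes held 1.83% of counts (95% Wilson interval 1.81% to 1.85%; group median 0.0975%), INS stood at 7803 CPM (median 160) and GCG at 1925 CPM (median 52.5). In the High pancreas library of 16CS60, the 10 most abundant genes held 30.4% of counts (95% Wilson interval 30.3% to 30.5%; group median 41.9%). That library also held 6.47 CPM of MYO7B (group median 0.165), 2.70 CPM of E2F2 (0.165) and 2.16 CPM of SLC17A2 (0.125). The High pancreas library of 15LS29 held 13840 CPM of PLA2G1B, where the group median was 25819, and the Low pancreas library of 12FS161 held 8.05 CPM of SYT7, where it was 33.8. Among High islets, 12FS161 held 1.13 CPM of CNNM1 in a group that reached 4.32 CPM. The High islets of 15AS28 held 20.4 CPM of PPY (median 78.0) and 9.27 CPM of EFNB3 (21.3). Among Low islets, 16IS5 held 9.77 CPM of ENTPD3 (median 26.9) and 12FS162 held 56.2 CPM of KDM6A (95.2). By a test of the difference between tissues, the density difference was unlike in islets and pancreas for 5718 genes.

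The 4283 genes that passed between High and Low pancreas, and the 5718 of the difference between tissues, may follow islet density, the counts of the 7 shallow libraries or another property of those libraries. Counts of the Y-linked genes KDM5D and EIF1AY were present in 4 of 8 High and 1 of 9 Low pancreas libraries. Few counts may have hidden them in shallow libraries. The shallow Low library of 12FS135 held 1 such count, and the islets of that animal held 136 and 212. The islets of the 6 animals with the code 14 held none. The sex of the animals may therefore be uneven between these groups too, and it was not fitted in pancreas. Counting noise alone was argued against. When every library was thinned to 265000 counts, 878 genes passed, which fell under the bound set beforehand for noise. That bound ignored that thinning left 2382 genes to test. Of these 36.9% passed, where noise at equal totals would leave almost none. With all counts 40.3% of 10634 tested genes passed, a larger set, so the 2 shares are not of the same genes. Of the 878, 496 had passed with all counts in the same direction and 382, all lower in High, had not. The folds lay a median of −0.74 from those with all counts while correlating with them at 0.985. Between the 7 shallow libraries and the 2 deeper ones of the same Low label 2278 genes passed (1114 higher and 1164 lower), which shows a difference within that label but does not isolate a property of the shallow libraries from density or animal, since both deeper ones come from animals with High islets and 6 of the 7 shallow ones have the code 14. Whether reads from outside mature transcripts contribute cannot be told apart from other properties, since olfactory receptor genes held a median of 248 CPM in the shallow libraries against at most 92.7 in a deeper pancreas library, a ratio of 2.68 where 3 had been asked. Islet density stays open: over the genes that passed, the fold of the 2 deeper Low libraries rose with that of the shallow ones with a slope of 0.207 (0.185 and 0.229 singly), below the bound set beforehand against density but by less than the SD of single High libraries (0.117, range −0.109 to 0.255), and no High animal has the code 14. These genes were chosen by a comparison that held the same libraries, which can raise the slope, so the slope cannot decide the question.

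The libraries were also split 100 ways into groups of the same sizes, the real split included. Chance can be excluded for the genes between tissues (7726 in the real split, at most 1 in another, as large in 1 of 100). For the difference between tissues the real split gave the most (5718, at most 27, 1 of 100). That contrast holds the same 7 shallow pancreas libraries, all Low, and 61 genes passed with only libraries above 1000000 counts. How the shallow libraries fell in its other splits is not given here. The splits therefore cannot decide whether these genes follow the density label or that grouping. For the pancreas genes the real split also gave the most (4283, at most 4200, 1 of 100, a median of 0 in the others). The random pancreas split with 4200 genes had all 7 shallow libraries on the same side, as the real split does. The splits therefore cannot decide whether the pancreas genes follow the density label or the grouping of the shallow libraries. Among libraries above 1000000 counts no pancreas gene passed edgeR's test (1222 at an unadjusted p under 0.05). By the number of lists that passed with the preset correlation, chance cannot be excluded for the pancreas lists (7, at most 8, 10 of 100), the lists between tissues (11, at most 12, 9 of 100) or the islet lists (3, at most 13, 75 of 100). That number says little of single lists, and between tissues the pan-endocrine, beta cell and acinar lists passed with an estimated correlation too (adjusted p = 0.016, 0.016 and 0.0293). For the islet genes the comparison says nothing, since every split gives at least the 0 of the real one (100 of 100, at most 1). With the preset correlation lists passed in the other splits too, a median of 3 in pancreas, 6 between tissues and 4 in islets.

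KDM6A, an X-linked histone demethylase gene, had one of the smallest p-values between High and Low islets (−0.52, SE 0.15, unadjusted edgeR p = 0.0022), without passing. A candidate explanation is the sex of the animals, since counts of the Y-linked genes KDM5D and EIF1AY were present in 6 of 8 High and 1 of 9 Low libraries. With that presence as a covariate the difference of KDM6A between density groups was −0.10 (SE 0.16, unadjusted edgeR p = 0.523), and the 7 libraries with these counts lay −0.63 (SE 0.16, unadjusted edgeR p = 0.000662) from the 10 without, as that explanation needs. In that fit no gene passed edgeR's test for density (996 at an unadjusted p under 0.05) and 5 passed for the presence of these counts, TP53I11 at −1.57 (adjusted p = 0.0307) and 4 without a symbol. A contribution of islet density to KDM6A stays open, because the 2 properties overlap.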

How the results depend on the processing

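Chosen only after the data were seen were the fits with only libraries above 1000000 counts, to thinned counts, with the log2 total or the presence of KDM5D and EIF1AY as a covariate, without genes above 5% of a library, without shallow or atypical libraries, with TMM-scaled list levels, of the shares with each library left out, and of the tissue lists with a block. The number of pancreas genes, 4283, was 4356 with relative log expression and 4239 with upper-quartile scaling, 4753 with DESeq2 and 3617 with limma-voom, and 3305 to 5044 when each library was left out. It was 10836 with no low-count filter and 7587 with a filter of 1 CPM, which test more genes (24276 and 16043), and 2828 in animals with the same label in both tissues, where 4949 genes were tested and all Low libraries are shallow with the code 14, as for each pancreas value of that choice. It fell to 368 with the leading digits of the animal code as a covariate and to 878 of 2382 tested genes with thinned counts. No pancreas gene passed edgeR's test with the acinar level (615 at an unadjusted p under 0.05) or the log2 total (533) as a covariate. Acinar level and depth each largely coincide with the label, so these fits cannot separate them from it. None passed with the label of the other tissue (2311) or in libraries above 1000000 counts (1222), and the cause was not tested. The islet count was 0 in each alternative run and when each library was left out (0 to 0). The tissue count of 7726 was 15012 with no filter, 2881 for a fold above 2, 7808 without the 2 islet libraries whose source name reads Pancreas and 8839 without the shallow libraries and 12AS51. The difference between tissues, 5718 genes, was 8812 with no filter and 61 in libraries above 1000000 counts. With an estimated correlation, passing lists fell to 0 in pancreas, 0 in islets and 3 between tissues, and with fry they were 8, 0 and 17. In islets 7 lists passed in animals with the same label in both tissues and 7 with the label of the other tissue. No pancreas list level passed with the label of the other tissue (0) or above 1000000 counts (0). The latter says little, since 45 splits allow no exact permutation p below 0.0222. After adjustment over 27 lists, that value passes only if many lists reach it. The endocrine share of the pancreas passed with the former 2 choices of label (1.24, exact permutation p = 0.00433, and 1.17, exact permutation p = 0.0323). With each library left out, log2 differences of shares ranged from 2.90 to 3.31 (acinar) and 0.43 to 1.07 (endocrine) in pancreas, and from −0.55 to 0.36 and −0.19 to −0.069 in islets. GCG in pancreas kept its direction and gained a call without Low replicate 9 (1.97, adjusted p = 0.000461), with the pan-endocrine level as a covariate (1.55, adjusted p = 0.00289) and in animals with the same label (2.02, adjusted p = 0.000467). Directions turned for the following, and the cause was not tested. INS in pancreas was 1.77 with DESeq2, 1.86 without Low replicate 9, 1.36 with the pan-endocrine level as a covariate and 1.38 in animals with the same label, and SST was 0.59 with the label of the other tissue. The endocrine share of the pancreas, 0.59 and not past the threshold, was −1.44 in libraries above 1000000 counts (exact permutation p = 0.133) and −0.14 without genes above 5% of a library (exact permutation p = 0.892). With the acinar level as a covariate RPS12 was −0.048, ITGAM 0.55, HSPA8 −0.41 and PDIA4 −0.14, and with the log2 total ITGAM was 0.27 and HSPA8 −0.18. Between tissues ENSSSCG00000018061 and ENSSSCG00000018063 were −0.10 and −0.97 with DESeq2, and −0.14 and −1.03 without the 2 libraries named above. The default settings of DESeq2 can replace outlying counts, and whether they did so for these genes or INS was not checked. Islet lists that turned and passed were fibroblasts (adjusted p = 0.000321) and immediate early genes (0.000321) in animals with the same label, and with the label of the other tissue fibroblasts (1.58e-06), immediate early genes (0.000114), glycolysis (0.000548), proliferation (0.0189) and the unfolded protein response (0.0472). The ribosomal list between tissues turned without the shallow libraries and 12AS51 (adjusted p = 0.00569). In libraries above 1000000 counts, list levels turned to −0.085 (ductal), −0.30 (heat shock), −0.20 (unfolded protein response) and −0.10 (oxidative phosphorylation). Values of single genes otherwise kept their call in 2270 cases, lost it in 184 and gained it in 7. List tests did so in 178, 29 and 12 cases and list levels in 258, 28 and 7. Direction was compared only where at least 1 of the compared fits passed, so cases that kept their call without passing can include turned directions. In the shallow libraries, where 3 counts were worth 5.60 to 11.3 CPM, low genes were not measurable, and simulated changes of a log2 of 1 were called in 21% of cases.

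With the animal as a block, 6719 genes passed between tissues, against 7433 for the same animals without it, and the difference between tissues passed for 7452 in animals with the same label. The block turned ENSSSCG00000018061 to −0.055 and ended the call of COX1 (0.61, adjusted p = 0.0832). In the difference between tissues SST was 0.27 over all libraries, −1.35 and not past the threshold in animals with the same label, and −1.29 with the block (adjusted p = 0.0108), so that the choice of animals turned the direction and the block brought the call. The pairing left 5 tissue lists with an estimated correlation. It changed no other call of a named gene or list.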

Other observations

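The genes named here and the tests of the order of the labels were chosen only after the values were seen.

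Digestive enzyme genes were not in the proportion of the organ in every islet library. In the islets of animals 15LS29 and 16IS5, the carboxypeptidase gene CPA1 stood at 330 and 49.7 CPM and CEL, carboxyl ester lipase, at 116 and 32.5 CPM. The lipase gene PNLIP stood at 4.36 and 3.45 CPM in the same libraries and the carboxypeptidase gene CPB1 at 2.72 and 2.87 CPM. CPA1 was therefore 75.7 and 14.4 times PNLIP, where the 17 pancreas libraries lay between 0.818 and 3.31. At the ratio of the animal's own pancreas, 99.7 and 44.6 CPM of PNLIP would go with that much CPA1. In the islets of 12FS162, 16CS60 and 14HS27, which held 78.5, 34.7 and 24.5 CPM of CPA1, the ratio was 2.03, 1.53 and 1.55.

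Stress-responsive genes and a neuropeptide varied between islet libraries of the same label. DNAJB1, a heat shock co-chaperone, ranged from 16.7 to 246 CPM in High and from 22.9 to 581 CPM in Low islets, with 581 CPM in 14HS26, 499 CPM in 14HS27 and 127 CPM in 14HS7 against at most 63.5 CPM in the other Low islets. FOSB, an immediate early transcription factor, ranged from 2.39 to 297 CPM in High and from 1.15 to 138 CPM in Low islets. GAL, which encodes galanin, ranged from 2.78 CPM in the High islets of 15AS28 to 1256 CPM in the Low islets of 14ES73. In the same High islets of 15AS28 the 10 most abundant genes held 52.3% of counts, the highest share among islets with a density label. Transcripts typical of liver were highest in the pancreas libraries of 11KS28 and 15LS30, with ALB, albumin, at 830 and 823 CPM, and the apolipoprotein gene APOB at 98.1 and 151 CPM. The next highest ALB level was 144 CPM, in 16CS60, and the medians were 48.7 CPM in High and 10.9 CPM in Low pancreas. The medians of APOB were 3.84 CPM in High and 47.3 CPM in Low pancreas. The fibrinogen gene FGB had 272 counts in 11KS28, 247 in 15LS30 and 0 to 30 in the other pancreas libraries.

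The islets of animal 12AS51, which have no density label, held 6702589 counts, the highest total. Of these, 87.8% lay in the 10 most abundant genes (95% Wilson interval 87.79% to 87.84%), 74.6% in ENSSSCG00000018061 and ENSSSCG00000018063 (74.58% to 74.65%) and 0.936% in endocrine genes (0.929% to 0.944%). INS stood at 2086 CPM and GCG at 490 CPM, and 14839 genes had a count. In the islets of 12FS135, which held 4097479 counts, 20946 genes had a count, the highest number among the islets, and olfactory receptor genes held 40.3 CPM.

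The density labels of the pancreas and the islets differed in 5 of 16 animals, and these may reflect biology of the animals or an error in the list of samples. A plain shift of the islet labels by 2 places is excluded, since 4 of the 17 pancreas labels would then differ from the islet label. After the first 2 islet samples, the 18 islet labels with 1 removed do run in the same order as the 17 pancreas labels, and 10 of 48620 orders of the 18 labels contain that order (a share of 0.000206). Most animals have the same label in both tissues, which random orders do not keep, so that this share may be too small, and the test was drawn from the labels it was run on. Both deeper Low pancreas libraries, 12FS161 and 15LS30, come from animals whose islets were labelled High. 12FS135, another animal whose labels differ, is also the animal whose libraries did not match in the presence of KDM5D and EIF1AY counts. A true difference between the labels of an animal's tissues stays open.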
